A study of Mus musculus with 3 samples.

How the data were processed

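Total RNA from 3 cultures of 32Dcl3 cells, a mouse myeloid progenitor line that grows in interleukin-3, was profiled on Affymetrix arrays, per the labels. The cells had received a retroviral vector that was empty (pMIG), that carried the unspliced form of Xbp1 (Xbp1U) or that carried its spliced form (Xbp1S). They were harvested after 24 hours, all with interleukin-3 at 10 ng per ml, per the labels' protocols. Each group holds 1 array, so there are no replicates, no p-value was computed and no error can be given for any single value.

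The deposited table holds 1 intensity per probe set and array, on a linear scale, for 45101 probe sets. The submitters' processing notes name MAS5, Affymetrix's algorithm that condenses the probes of a set into 1 signal. Its version, scaling target and masking are not given in the sources used here, and the table carries no detection calls. The median signal was 15.0 on the pMIG array, 12.9 on the Xbp1U array and 14.9 on the Xbp1S array. The means after trimming 2% of values at each end were 130.3, 124.0 and 117.3, so the arrays do not share an equal scale over all probe sets.

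Probe sets were named through the platform annotation. Of the 35890 probe sets it listed, 34958 had exactly 1 gene and 932 had several, which were not named. The Entrez identifiers of 34754 matched the RefSeq gene table of GRCm38.p6 and no symbol changed. A further 9160 probe sets had no gene here, and 64 were Affymetrix controls. No coordinates are given, because the table names no genome build. Some members of the fixed lists had no probe set with exactly 1 gene and are not analysed here.

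The rules that follow were fixed before the data were examined. Signals were raised to a floor of 9.04, the 40th percentile of all values on the 3 arrays, and converted to log2. Each of 18194 genes was represented by its probe set with the highest mean over the arrays, and a gene counted as measured if it exceeded the floor on at least 1 of the 2 arrays compared. Genes with a ratio of at least 2-fold were counted. Values at the floor give only a bound. The genes named are Xbp1, then in each of the 3 comparisons the 8 highest and 8 lowest ratios among genes above the floor on both arrays. The 2 largest bounds in each direction were added, and the 2 highest and 2 lowest members of each gene list in Xbp1S against pMIG. Identifiers without a gene name were counted and not named. Other genes are marked in the text as chosen after their values were seen.

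There were 26 gene lists holding 659 entries, of which 607 could be placed on the array. Each list's median log2 ratio was ranked among the medians of 10000 random lists of the same size, matched on mean expression in 10 bins. The percentile describes these arrays and is not a p-value. A list is said to stand apart if it fell under the 0.5th or above the 99.5th percentile. Over 78 combinations of list and comparison, no correction was applied. Because both comparisons with pMIG share 1 array, 100 simulations of unchanged arrays with noise of the observed size at each level gave the correlation that the shared array alone produces.

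Alternatives fixed in advance were median centring, quantile normalization, log2 of the signal plus 1 or plus 32 without a floor, and a floor at the 60th percentile (26.5). Others were the mean of all probe sets of a gene, leaving out probe sets that can match several transcripts, every probe set on its own, thresholds of 1.5-fold and 3-fold, and unmatched random lists. A floor at the 75th percentile (107.1) and scalings to the bacterial spike-in probe sets or to the median ratio of genes above the 60th percentile were chosen after seeing the data. No array could be left out. Computations used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9. In 1 simulation of Xbp1S against pMIG with 12494 measured genes, 49 of 50 genes raised by 1.5 on the log2 scale passed 2-fold, as did 50 of 50 raised by 3. For genes lowered by the same amounts these were 49 of 50 and 50 of 50. All changed genes were drawn from those with a mean signal above 26.5, so recovery of dim genes was not tested. Of 12269 unchanged genes, which included dim ones, 303 passed (2.47%). The simulated noise was sized from the spread between the Xbp1U and pMIG arrays and was equal on all arrays, without a shift in scale. With no replicates to size it from, this share is not an error rate of the real comparisons. Of 100 unchanged lists, 5 fell outside the central 95% of random lists. These lists were drawn at random from genes with independent noise, so a number near this was set by the design. It does not describe lists of related genes.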

Results

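Gene expression was measured in 32Dcl3 cells harvested after 24 hours that had received an empty retroviral vector, unspliced Xbp1 or spliced Xbp1. Xbp1 is a transcription factor of the unfolded protein response, and splicing of its mRNA by Ire1 produces the active form. The comparisons ask how each form altered the transcriptome relative to the empty vector and how the forms differed. With 1 array per group there were no replicates, so all differences below are between single arrays. The share of probe sets above the floor was 60.7% in pMIG, 57.8% in Xbp1U and 61.5% in Xbp1S. The ratio of 3' to 5' beta-actin signals, a measure of RNA integrity, was 1.34 in pMIG, 1.32 in Xbp1U and 1.44 in Xbp1S. The same ratio for Gapdh was 0.701, 0.730 and 0.692.

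Xbp1 was represented by 4 probe sets. The brightest read 4102 in pMIG, 4230 in Xbp1U and 5327 in Xbp1S, so that Xbp1S was 1.30-fold above pMIG. The next read 4081, 4402 and 5136, and another 1483, 1322 and 1828. The dimmest read 175, 158 and 164. In Xbp1U the ratio to pMIG ran from 0.892 to 1.08 over these probe sets. Where the probes lie in the transcript is not given in the sources used here, so these signals separate neither the spliced from the unspliced form nor the vector from the endogenous transcript. The identity of the arrays therefore rests on the labels.

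Spliced Xbp1 was compared with the empty vector first. Genes of the secretory pathway were higher in the Xbp1S array across all 5 lists that describe it. Of 39 measured genes for transport from the endoplasmic reticulum (ER) to the Golgi, 30 were at least 2-fold higher and 0 at least 2-fold lower, with a median log2 ratio of 1.33. They were led by Sec24d, a cargo adaptor of the COPII coat, at 200 in pMIG and 2168 in Xbp1S (10.9-fold), and by Arfgap3, an Arf GTPase activator, at 81.5 and 656. Among 29 ER chaperones and folding enzymes, 19 were at least 2-fold higher and 1 lower, with a median of 1.11. The co-chaperone Dnajb9 read 380 in pMIG and 3446 in Xbp1S (9.06-fold), and Fkbp14, under the floor in pMIG, was at least 6.71-fold higher, although its other probe set above the floor read lower.

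The 25 genes for translocation and signal peptide processing had a median log2 ratio of 0.93, with 11 at least 2-fold higher. Srprb, a subunit of the signal recognition particle receptor, was 5.31-fold higher and the signal peptide peptidase H13 3.07-fold. Of 23 genes of ER-associated degradation, 8 were at least 2-fold higher (median 0.80), including Herpud1 at 5.25-fold and Edem2 at 3.83-fold. The median of 28 N-glycosylation genes was 0.79, and 6 were at least 2-fold higher, among them Pgm3 at 5.76-fold and Gmppb at 5.69-fold, which make sugar nucleotide donors. All 5 medians exceeded those of every matched random list, whose own medians lay between -0.25 and -0.23. After scaling to the spike-ins, chosen after seeing the data, the numbers at least 2-fold higher were 33 for ER to Golgi transport, 22 for chaperones, 18 for translocation, 16 for N-glycosylation and 15 for degradation. The lowest members were dim or little different. Derl3 read 28.2 in pMIG and 12.8 in Xbp1S, Fkbp11 19.6 and 8.44, Pdia5 13.2 and 3.56, and Tram2 39.8 and 22.3. Log2 ratios were 0.04 for Stt3b, -0.29 for Emc1 (1 of 2 other probe sets the other way), -0.54 for Tusc3, -0.48 for Alg6, -0.37 for Sec24b and -0.32 for Sar1b.

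Regulators of the unfolded protein response had a median log2 ratio of 0.38 over 17 genes (99.89th percentile). This list holds Xbp1, the transferred gene, and its median is the ratio of Xbp1 itself. The ER-tethered transcription factor Creb3l2 read 18.2 and 128, and Bfar was 4.93-fold higher, while Ern1, which encodes Ire1, had a log2 ratio of -0.60, with 2 of its 3 other probe sets above the floor going the other way. Bhlha15 read 17.5 and 10.4, both dim. The 35 measured targets of ATF4 and CHOP had a median of 0.22 (99.93rd percentile), with 7 at least 2-fold higher. Nupr1 read 52.3 and 260, Slc7a11 was at least 6.45-fold higher, Phgdh of serine synthesis read 3122 and 1818, and Stc2, dim in pMIG, was under the floor in Xbp1S. Without probe sets that can match several transcripts, the medians of the regulators and of the ATF4 and CHOP targets were 0.06 and 0.05 and their percentiles 96.2 and 96.7, so neither list stood apart in every alternative.

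**Figure D1:**
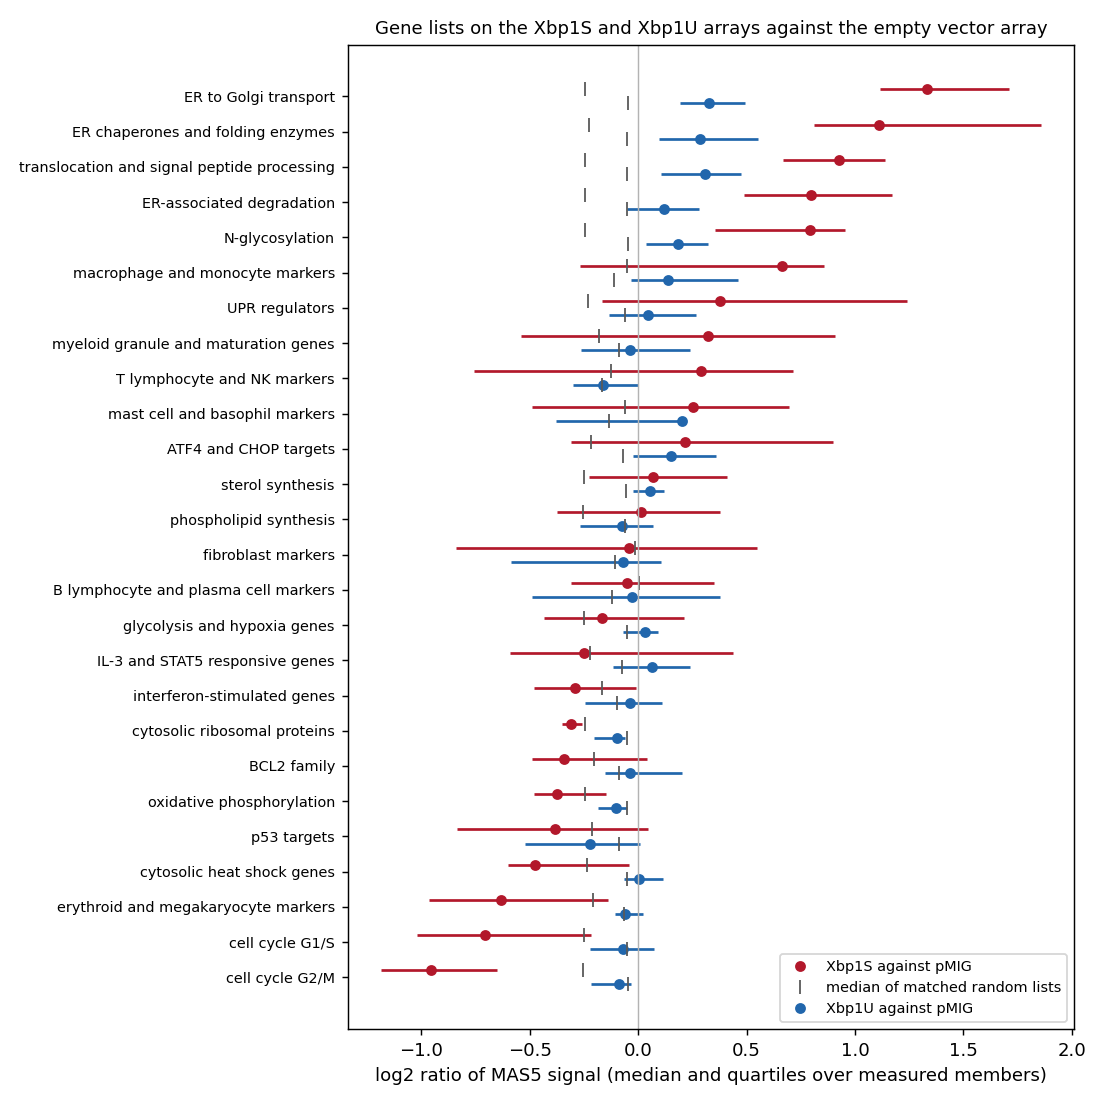
Median log2 ratio of each of the 26 gene lists in Xbp1S (red) and Xbp1U (blue) over pMIG, with lines for the quartiles over measured members and grey ticks for the median of matched random lists. The 5 secretory lists lie at 0.79 to 1.33 in Xbp1S and at 0.12 to 0.33 in Xbp1U, and the cell cycle lists at -0.71 and -0.96 in Xbp1S.

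Cell cycle genes were lower in the Xbp1S array. Of 26 genes of G2/M, 13 were at least 2-fold lower and 0 higher, with a median log2 ratio of -0.96. The spindle motor Kif11 read 1492 in pMIG and 462 in Xbp1S, and the kinetochore gene Cenpf 264 and 98. Of 26 genes of G1/S, 8 were at least 2-fold lower (median -0.71), including Pola1, the catalytic subunit of DNA polymerase alpha, at 463 and 174, and the primase Prim1 at 1240 and 483. Both medians lay below those of every matched random list, whose medians were -0.25 for G1/S and -0.26 for G2/M. Some members differed little, with log2 ratios of 0.32 for Cdc6, 0.25 for Cdc45, 0.17 for Cdc20 and -0.23 for Cdk1. Of the other probe sets above the floor, 1 of 2 for Cenpf, 1 of 2 for Cdc20 and the 1 for Cdc45 went the other way. After scaling to the spike-ins the medians were -0.64 for G2/M and -0.39 for G1/S, still below every matched random list, with 3 and 2 genes at least 2-fold lower.

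Lineage genes went in both directions. Of 21 myeloid granule and maturation genes, 4 were at least 2-fold higher and 2 lower (median 0.32, 99.84th percentile, 99.49th without probe sets that can match several transcripts). Gfi1, a transcriptional repressor required for neutrophil development, was 4.98-fold higher and the granule protein Lcn2 4.63-fold, whereas Mpo was 2.48-fold lower and Anxa1 2.34-fold. Of 14 macrophage and monocyte markers, 3 were at least 2-fold higher (median 0.66, 99.83rd percentile), and the percentile was 97.6 with the mean of all probe sets. Cd68 read 132 in pMIG and 447 in Xbp1S, Cd14 611 and 1512, Lgals3 19.1 and 6.52, and Trem2 16.1 and 2.66. The 11 erythroid and megakaryocyte markers had a median of -0.63 (1.17th percentile, not past the limit set, and 0.40 to 35.6 over the alternatives), with Gata1 2.22-fold and Klf1 2.19-fold lower, Itga2b at a log2 ratio of 0.10 and Car1 under the floor in pMIG and just above it in Xbp1S.

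The other lists did not stand apart in the deposited values. Their median log2 ratios were 0.07 for sterol synthesis, 0.01 for phospholipid synthesis, -0.17 for glycolysis and hypoxia, -0.25 for IL-3 and STAT5 responsive genes and -0.29 for interferon-stimulated genes. They were -0.31 for cytosolic ribosomal proteins, -0.34 for the BCL2 family, -0.38 for oxidative phosphorylation, -0.38 for p53 targets and -0.48 for cytosolic heat shock genes. For markers of other cell types they were 0.25 for mast cells and basophils, 0.29 for T lymphocytes and NK cells, -0.05 for B lymphocytes and plasma cells and -0.04 for fibroblasts. The mast cell median turned to -1.23 (0.25th percentile) with the floor at the 75th percentile, where Slc18a2 and Gata2 were the only members measured. Within these lists, Bcl2 read 499 in pMIG and 205 in Xbp1S, Pim2 175 and 74.0, Id1 1314 and 628, and the cytokine gene Osm 108 and 391. Lpin1, of lipid synthesis, was 4.38-fold higher, Insig1 2.31-fold and Trim30a 5.17-fold, and the mast cell genes Slc18a2 and Gata2 were 2.74-fold and 2.01-fold lower while Mcpt8 was 2.94-fold higher, and 7 of 11 measured members read above 0.

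Over all 13876 measured genes, 835 were at least 2-fold higher and 1031 at least 2-fold lower in Xbp1S. Among genes above the floor on both arrays the highest ratio was that of the RNA exonuclease Isg20, at 17.0 in pMIG and 1514 in Xbp1S (88.9-fold), followed by Clec4e at 15.7-fold, Celsr2 at 15.3-fold and Smim14 at 13.8-fold. The pMIG signals of Isg20, Clec4e and Celsr2 were under 26.5, and with the floor at that level their log2 ratios were 5.84, 3.81 and 3.19, so the exact folds and ranks of dim genes are uncertain. Plpp5, Kctd14 and Stab1 lay between 10.1-fold and 10.4-fold. Csn3, which encodes kappa-casein, was at least 86.2-fold higher and Slc46a3 at least 13.9-fold. The lowest ratio (9.72-fold lower) belonged to 1 identifier without a gene name. It was followed by Rdm1 at 7.20-fold, Slco2b1 at 7.07-fold, H2bc21 at 6.34-fold, the hematopoietic gene Hemgn at 6.30-fold, Pglyrp2 at 5.87-fold, Trgv4 at 5.52-fold and Tmem158 at 5.36-fold lower, and all but Hemgn and Trgv4 read under 26.5 in Xbp1S. For Tmem158, 1 of 2 other probe sets above the floor went the other way. Usp49 was at least 8.87-fold lower and Pramel18 at least 7.77-fold. H2bc21 turned to a log2 ratio of 0.18 without probe sets that can match several transcripts. The balance of directions depended on scaling: 44.7% of called genes were higher as deposited and 45.1% after median centring. It was 60.2% after quantile normalization, 73.7% after scaling to expressed genes and 78.8% after scaling to spike-ins. The median log2 ratio of all measured genes was -0.15 as deposited and 0.13 after spike-in scaling.

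**Figure D2:**
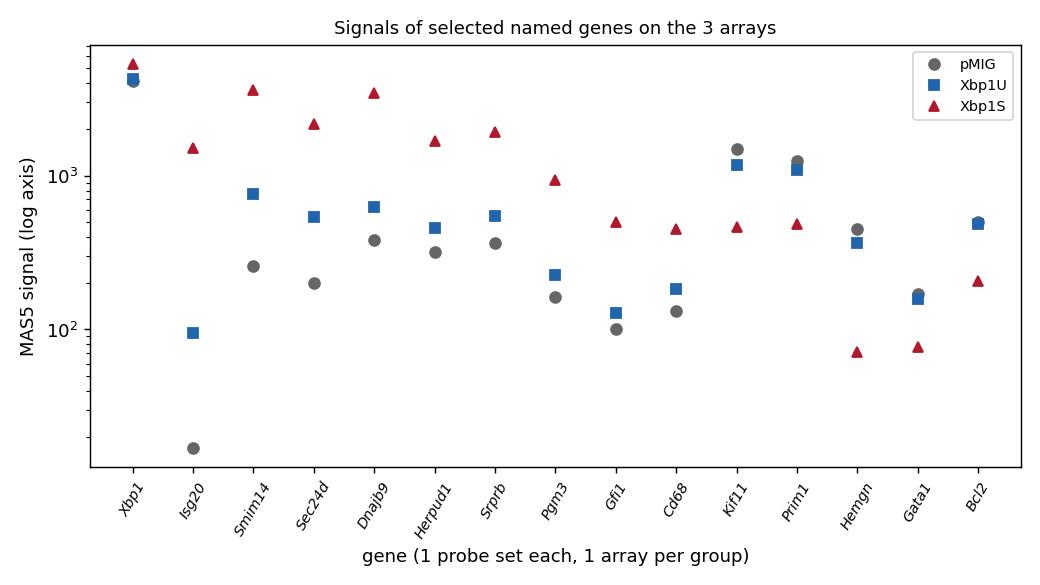
MAS5 signal on a log axis of 15 of the named genes, picked for display after their values were seen, with 1 point for each array. Isg20 read 17.0, 95.2 and 1514 in pMIG, Xbp1U and Xbp1S, and Kif11 read 1492, 1170 and 462.

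Unspliced Xbp1 was then compared with the empty vector. Differences were smaller, and the same 5 secretory lists and the ATF4 and CHOP targets stood apart as higher. The median log2 ratio was 0.33 over 39 ER to Golgi transport genes, 0.31 over 25 genes of translocation and signal peptide processing and 0.29 over 29 ER chaperones and folding enzymes. It was 0.19 over 28 N-glycosylation genes and 0.12 over 23 genes of ER-associated degradation. All were at or above the 99.95th percentile of matched random lists, whose medians were about -0.05, but only 2 genes, both of ER to Golgi transport, reached 2-fold higher in these lists. Sec24d read 200 in pMIG and 535 in Xbp1U (2.68-fold), Dnajb9 380 and 624, Edem2 227 and 378 and Srprb 362 and 549.

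Targets of ATF4 and CHOP had a median of 0.15 over 35 genes (100th percentile), and 3 were at least 2-fold higher. Nupr1 was 2.75-fold and Slc7a11 at least 3.39-fold higher. Cell cycle genes did not stand apart, with medians of -0.07 for G1/S (30.4th percentile) and -0.09 for G2/M (14.4th percentile), and Kif11 read 1492 and 1170. Neither did regulators of the unfolded protein response (0.04), erythroid and megakaryocyte markers (-0.06), macrophage and monocyte markers (0.14) or myeloid granule and maturation genes (-0.04). Mpo read 288 in pMIG and 144 in Xbp1U, a 2.00-fold difference.

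In all, 142 of 13437 measured genes were at least 2-fold higher in Xbp1U and 403 lower. Among genes above the floor on both arrays, Isg20 (5.59-fold), Slc31a2 (4.42-fold), Apc2 (3.62-fold) and Smim14 (2.94-fold, at 259 and 762) were highest, followed by Zscan20, Clec4e, B3gntl1 and Nupr1. The bounds were led by Gdf2 (at least 4.44-fold) and Slc9a8 (at least 4.43-fold). The other probe set above the floor for Apc2 and for Clec4e, and 1 of 3 for Slc9a8, went the other way. The 8 lowest were Rpl39 (7.62-fold), Prg2 (4.99-fold), Plxna1, Csdc2, Hoxa9, Eldr, Srms and Ptpn14, which read between 36.2 and 83.7 in pMIG, and Cphx3 and Gfra2 were at least 5.36-fold and 4.89-fold lower. Nearly all of these calls involved dim genes: with the floor at the 60th percentile 13 genes were higher and 42 lower, and with the floor at the 75th, chosen after seeing the data, 4 and 11. Of the called genes 26.1% were higher as deposited, 42.8% after spike-in scaling, 50% after quantile normalization and 53% after median centring.

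The spliced form was compared directly with the unspliced form last. Secretory genes were again higher in Xbp1S, with medians of 1.06 for ER to Golgi transport (21 of 39 at least 2-fold), 0.81 for ER chaperones and folding enzymes (11 of 28), 0.73 for ER-associated degradation (7 of 23), 0.60 for translocation and signal peptide processing (3 of 25) and 0.51 for N-glycosylation (5 of 28). Each lay above every matched random list. Cell cycle medians were -0.82 for G2/M (7 of 26 at least 2-fold lower) and -0.60 for G1/S (5 of 26), below every matched random list. Median centring left 15, 10, 3, 1 and 3 secretory genes at least 2-fold higher in that order of lists, and spike-in scaling 26, 14, 9, 7 and 8; for G2/M and G1/S the numbers lower were 13 and 8, and 3 and 4. Myeloid granule and maturation genes had a median of 0.37 (99.68th percentile, reaching 96.3 under an alternative), and erythroid and megakaryocyte markers of -0.57 (0.47th percentile, reaching 13.1 under an alternative). Gfi1 was 3.91-fold higher, and Gata1 and Klf1 were 2.04-fold and 2.26-fold lower. In the deposited values, 3 lists that stood apart against pMIG did not do so here. They were ATF4 and CHOP targets (median 0.09, 96.2nd percentile), regulators of the unfolded protein response (0.20, 97.7th) and macrophage and monocyte markers (0.44, 92.8th).

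Between these arrays 889 of 13670 measured genes were at least 2-fold higher in Xbp1S and 557 lower. With both arrays above the floor, the highest were Csn3 (33.9-fold), Isg20 (15.9-fold), Mir22hg (9.92-fold), Atl1 (9.31-fold), Fam131a (8.90-fold), Rrad (7.69-fold), Kctd14 (7.64-fold) and Rnf183 (7.57-fold), with Hpca at least 9.81-fold and Sytl1 at least 7.31-fold higher. The lowest were Rdm1 (7.28-fold), Pglyrp2 (5.22-fold), Hemgn (5.13-fold), P2ry1 (4.95-fold), Baiap2 (4.26-fold), Ccnb1ip1 (4.24-fold, at 1029 and 242), Car13 (4.23-fold) and Tfeb (4.22-fold), with Fhod1 at least 5.07-fold and H1f10 at least 4.72-fold lower. Of the highest genes Csn3, Atl1, Fam131a, Rrad and Rnf183 read under 26.5 in Xbp1U, where their log2 ratios at that floor were 4.88, 2.40, 2.41, 2.25 and 1.64, and of the lowest all but Hemgn and Ccnb1ip1 read under 26.5 in Xbp1S. Baiap2 turned to a log2 ratio of 0.56 without probe sets that can match several transcripts. Of the called genes 61.5% were higher as deposited, 34.2% after median centring, 78.8% after spike-in scaling and 79.6% after scaling to expressed genes.

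Across the 10479 genes above the floor on all 3 arrays, the log2 ratios of Xbp1S and Xbp1U to pMIG had a Pearson r of 0.45. Genes are not independent replicates. The simulation gave r of 0.50, but it put equal noise on the 3 arrays, which fixes r near that value whatever the data. Its noise was sized from the spread between Xbp1U and pMIG, so any real difference between them counted as noise. The simulated values below therefore cannot tell a shared effect from the shared array. The covariance was 0.106, against 0.0591 simulated. At least 2-fold higher in both were 23 genes, against 2.33 for independent lists and 29.3 simulated, and 38 were lower in both, against 12.0 and 28.4. The controls cannot be split, so part of any excess may come from the shared array. Taking the covariance from the variance of each ratio left 0.357 for Xbp1S and 0.0124 for Xbp1U, which turned negative under 3 alternatives. By the same reckoning the part of pMIG is the covariance itself, 0.106, larger than that of Xbp1U. This part holds noise of the pMIG array together with any effect that both forms share.

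**Figure D3:**
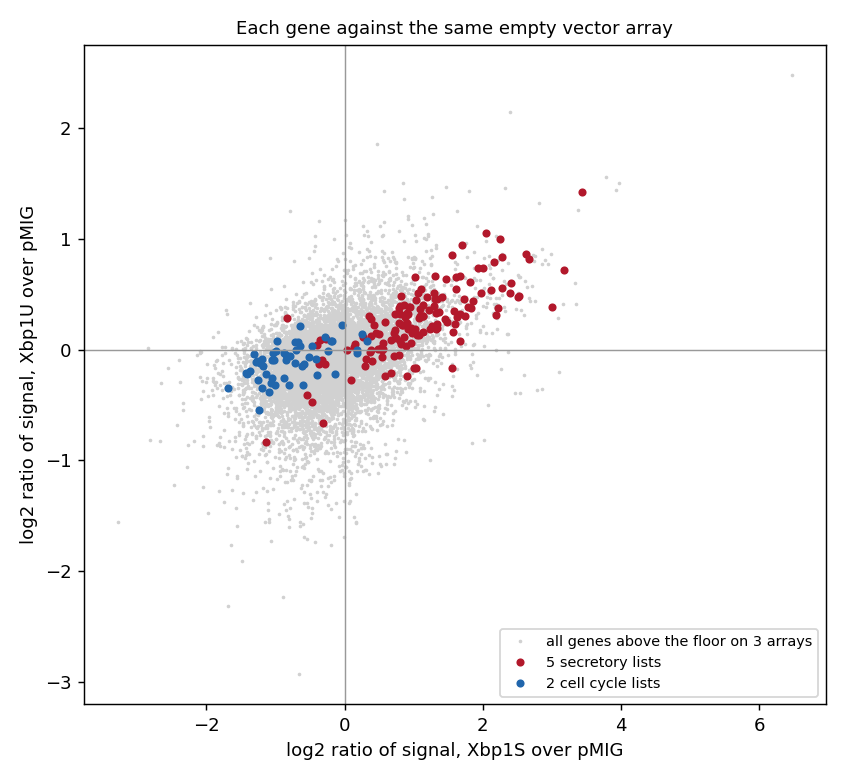
Each point is a gene above the floor on all 3 arrays, placed by its log2 ratio of Xbp1S over pMIG (horizontal) and of Xbp1U over pMIG (vertical), so both axes share the pMIG array. Secretory genes (red) lie mostly to the right of 0 and, less far, above it, and cell cycle genes (blue) lie mostly to the left, with G2/M at a median of -0.96 in Xbp1S and -0.09 in Xbp1U.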

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

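The tests on array scaling, noise independent between genes, dilution and the difference of shares below were chosen only after the results they bear on were seen, that on the spread of shares after the difference of shares, and the other filters of the test on genes chosen without pMIG after its first form. Among the 9160 probe sets without a gene here, which no comparison of genes used, 6 were at least 4-fold higher in Xbp1S than in pMIG with a signal above 107.1, and 2 were lower. No such probe set was higher or lower in Xbp1U than in pMIG. Their identity is not analysed here.

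Most expressed genes read lower in Xbp1S than in pMIG, with a median log2 ratio of -0.25 over 9022 genes. The bacterial spike-ins, added in fixed amounts, also read lower, with a median of -0.31 over 15 probe sets (95% interval of the median -0.39 to -0.22), so array scaling may account for this general shift. The excess of lower over higher genes in the deposited values therefore cannot be separated from array scaling and is not read as biology.

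For the slightly higher secretory genes in Xbp1U than in pMIG, array scaling is argued against: 1 factor per array moves all genes alike, and after quantile normalization, which need not, the pooled secretory median exceeded that of all measured genes by 0.32 (95% interval 0.24 to 0.37). Chance noise of the pMIG array that is independent between genes is argued against, since the pooled median of 144 secretory genes was 0.26 (95% interval 0.19 to 0.31, 118 above 0), against -0.05 in matched random lists. A pMIG culture low in secretory transcripts as a group stays open with 1 such array. Genes at least 2-fold higher in Xbp1S than in Xbp1U, a choice made without pMIG, cannot settle it. Such a culture may pass the limit set before the result as well. The 532 of 889 above 26.5 in Xbp1S or Xbp1U and measured in Xbp1U or pMIG had a median of 0.013 (100th percentile). All 889 had one of -0.05 (99.77th), also past that limit. The 761 measured in Xbp1U or pMIG had -0.21 (percentile 0), but this filter drops genes at the floor on both arrays, whose ratio is 0. Choosing genes for a low Xbp1U reading also lowers this ratio, so that value decides nothing. Of the 889, the 47 secretory genes had a median of 0.39 (95% interval 0.30 to 0.52, 43 above 0 and 4 below). The 842 others had -0.09 (66.2nd percentile). Carry-over of Xbp1S RNA or cells into the Xbp1U sample stays open too, and it needs 1 constant share of the Xbp1S difference. The median shares were 14.4% in secretory and 10.8% in other genes, a difference of 3.69 points (95% interval 0.75 to 9.09). After a first run with 2 scalings the test was widened to 15 combinations of scaling and fold range. All 15 differences were above 0, from 2.01 to 6.23 points, but only 8 had an interval that excluded 0. The combinations use the same arrays and overlapping genes, so they are not separate tests. The interquartile range of the share in 119 genes at least 4-fold higher was 9.30 points against 6.79 simulated for a constant share (95% of simulations 5.46 to 8.30), which rests on a modelled noise and decides nothing alone; a weak activity of the unspliced construct, or its splicing in the cells, was not tested and may equally give such shares.

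Cell cycle genes read lower in Xbp1S than in pMIG. Array scaling as the whole cause is argued against, since the pooled median of 52 genes was still -0.53 after scaling to the spike-ins (95% interval -0.72 to -0.33). Dilution by more abundant secretory transcripts is argued against by the difference of -0.53 between cell cycle genes and ribosomal protein and oxidative phosphorylation genes (95% interval -0.72 to -0.33), which dilution would lower alike. The 95% intervals for the difference of shares and for the difference from ribosomal protein and oxidative phosphorylation genes came from a bootstrap. The other 95% intervals here and above are binomial intervals of a median. Both kinds treat genes or probe sets as independent, which the genes of a list are not. An effect of spliced Xbp1 on proliferation remains a hypothesis, and differences between single cultures in density or growth phase, for which 1 array per group gives no test, may give the same values.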

How the results depend on the processing

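The 3 settings that floor at the 75th percentile or scale to spike-ins or expressed genes were chosen after seeing the data. The list medians that stood apart kept their sign under every alternative run, and of the list medians under alternatives 686 stayed within the 95% interval of the main median and 91 moved. Of 4527 log2 ratios of named genes under alternatives, 3557 moved by less than the spread of the arrays at their level, 966 moved further and 4 reversed. Unmatched random lists change only percentiles and are left out of these totals. Counts moved with the fold threshold, the floor or offset for dim signals and the scaling, and the cause was not tested. No array could be left out with 1 per group, and no detection calls were at hand to say which dim signals exceed background.

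After median centring, counts were 283 higher and 251 lower in Xbp1U against pMIG, 1173 lower in Xbp1S against Xbp1U. After median centring, list medians in Xbp1U against pMIG were 0.33 for ER-associated degradation, 0.52 for translocation, 0.40 for N-glycosylation, 0.54 for ER to Golgi transport, 0.37 for ATF4 and CHOP targets. After median centring, list medians in Xbp1S against Xbp1U were 0.60 for ER chaperones, 0.39 for translocation, 0.30 for N-glycosylation, -0.81 for G1/S, -1.03 for G2/M. After quantile normalization, counts were 675 lower in Xbp1S against pMIG, 246 higher and 246 lower in Xbp1U against pMIG. After quantile normalization, list medians in Xbp1S against pMIG were 0.98 for N-glycosylation. After quantile normalization, list medians in Xbp1S against Xbp1U were 0.62 for N-glycosylation. After quantile normalization, the variance left after taking off the covariance was 0.00603 for Xbp1U. With log2 of the signal plus 1, counts were 1578 higher and 1637 lower in Xbp1S against pMIG, 686 higher and 1169 lower in Xbp1U against pMIG, 1731 higher and 1112 lower in Xbp1S against Xbp1U. With the floor at the 60th percentile, counts were 466 higher and 642 lower in Xbp1S against pMIG, 13 higher and 42 lower in Xbp1U against pMIG, 369 higher and 354 lower in Xbp1S against Xbp1U. With the floor at the 60th percentile, the variance left after taking off the covariance was -0.0138 for Xbp1U. With log2 of the signal plus 32, counts were 362 higher and 315 lower in Xbp1S against pMIG, 7 higher and 17 lower in Xbp1U against pMIG, 272 higher and 145 lower in Xbp1S against Xbp1U. With log2 of the signal plus 32, the variance left was 0.223 for Xbp1S and -0.0102 for Xbp1U, and the covariance was 0.0584. With the mean of all probe sets, counts were 83 higher and 212 lower in Xbp1U against pMIG. With the mean of all probe sets, list medians in Xbp1U against pMIG were 0.20 for ER to Golgi transport. With the mean of all probe sets, list medians in Xbp1S against Xbp1U were -0.60 for G2/M. Without probe sets that can match several transcripts, the variance left after taking off the covariance was 0.0224 for Xbp1U. Without probe sets that can match several transcripts, log2 ratios turned to 0.56 for Baiap2 in Xbp1S against Xbp1U, 0.26 for Fkbp11 in Xbp1U against pMIG, 0.18 for H2bc21 in Xbp1S against pMIG, 0.19 for H2bc21 in Xbp1S against Xbp1U. With the floor at the 75th percentile, counts were 331 higher and 331 lower in Xbp1S against pMIG, 4 higher and 11 lower in Xbp1U against pMIG, 249 higher and 174 lower in Xbp1S against Xbp1U. With the floor at the 75th percentile, list medians in Xbp1S against pMIG were 1.31 for macrophage markers. With the floor at the 75th percentile, the variance left after taking off the covariance was -0.0235 for Xbp1U. Scaled to the spike-ins, counts were 1522 higher and 409 lower in Xbp1S against pMIG, 243 lower in Xbp1U against pMIG, 357 lower in Xbp1S against Xbp1U. Scaled to the spike-ins, list medians in Xbp1S against pMIG were 1.11 for ER-associated degradation, 1.24 for translocation, 1.11 for N-glycosylation, 0.54 for ATF4 and CHOP targets, -0.64 for G2/M. Scaled to the spike-ins, list medians in Xbp1U against pMIG were 0.27 for ER-associated degradation, 0.46 for translocation, 0.33 for N-glycosylation, 0.47 for ER to Golgi transport. Scaled to the spike-ins, list medians in Xbp1S against Xbp1U were 0.68 for N-glycosylation, -0.65 for G2/M. Scaled to expressed genes, counts were 1384 higher and 494 lower in Xbp1S against pMIG, 340 lower in Xbp1S against Xbp1U. Scaled to expressed genes, list medians in Xbp1S against pMIG were 1.05 for ER-associated degradation, 1.18 for translocation, 1.05 for N-glycosylation. Scaled to expressed genes, list medians in Xbp1S against Xbp1U were 0.69 for N-glycosylation, -0.64 for G2/M. Counting every probe set, counts were 1735 higher and 2295 lower in Xbp1S against pMIG, 375 higher and 1097 lower in Xbp1U against pMIG, 2002 higher and 1240 lower in Xbp1S against Xbp1U. At 1.5-fold, counts were 1983 higher and 3166 lower in Xbp1S against pMIG, 606 higher and 1386 lower in Xbp1U against pMIG, 2239 higher and 2195 lower in Xbp1S against Xbp1U. At 3-fold, counts were 252 higher and 147 lower in Xbp1S against pMIG, 18 higher and 53 lower in Xbp1U against pMIG, 210 higher and 70 lower in Xbp1S against Xbp1U.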

Other observations

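The 1 test in this part was written before its result was seen. Of 11 erythroid and megakaryocyte markers 9 read lower in Xbp1S than in pMIG (1.17th percentile, 0.40 to 35.6 over the alternatives). The list stood apart in Xbp1S against Xbp1U (0.47th percentile), but reached 13.1 under an alternative. Of 11 mast cell and basophil markers 7 read higher in Xbp1S than in pMIG and 4 lower. That list did not stand apart (80.9th percentile, 0.25 to 95.7 over the alternatives). Chosen after their values were seen, Tal1 read 615 in pMIG, 569 in Xbp1U and 307 in Xbp1S, and Tfrc, the transferrin receptor, read 1914, 1860 and 1008, whereas Pf4 read 116, 109 and 102 and Gp9 246, 236 and 227. Among genes named by rule, Gata2 read 597, 695 and 297, and Mcpt8 read 20.1, 23.5 and 58.9. The control probe set for the B1 repeat read 2209 in pMIG, 1528 in Xbp1U and 932 in Xbp1S.

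Among genes above the floor on both arrays, Isg20 had the highest ratio in Xbp1S and in Xbp1U against pMIG, while 22 measured interferon-stimulated genes had a median log2 ratio of -0.29 in Xbp1S (22.5th percentile).

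A hypothesis was that genes lower in Xbp1S are also slightly lower in Xbp1U. For the 447 of 557 genes at least 2-fold lower in Xbp1S than in Xbp1U that had a signal above 26.5 in either, the median Xbp1U over pMIG ratio was -0.042, against -0.09 in matched random lists, and over all 557 it was -0.014. This by the rule written beforehand speaks against a graded fall. That rule was kept from deciding, because the prediction was poorly designed: choosing genes for a high Xbp1U reading lifts this ratio, so a small graded fall could be hidden and the question stays open.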
